A study of Marchantia polymorpha with 12 samples.

How the data were processed

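RNA was measured in 12 libraries of Marchantia polymorpha gemmalings that fall into 4 groups of 3. The groups were wild type Tak-1 and the Mphy5 mutant, each with and without 3 h of added UV-B. Libraries were Illumina TruSeq and were read as single ends of 100 bases on a NovaSeq, per the labels' protocols. The labels number the replicates of each group from 1 to 3 but do not say whether they came from separate cultures, so p-values measure only the spread between these samples.

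Reads were aligned with STAR 2.7.4, per the submitters' processing notes. The genome build, the annotation, the counting program, its use of strand and its treatment of reads that match several genes are not given in the sources used here. The deposited table holds a normalized signal per gene, which the values show to be read counts divided by 1 size factor per library. In each library 100% of the nonzero values were whole multiples of 1 step within a tolerance of 0.02 reads. The step multiplied by a median-ratio size factor came to 1.00 in every library, so whole reads could be recovered. Recovered totals were 44787979 to 67532310 reads per library. A floor of 3 reads per library corresponds to 2.34 to 3.58 normalized reads, and floors cover counting error only.

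Names came from a RefSeq gene table of assembly MpTak2_v7.1, which was used for names and for the order of genes but not for coordinates. Of the 18255 gene identifiers in the file, 18082 (99.1%) carried a locus number found in that table, and 3110 had a symbol. Of the 1729 locus numbers missing from the table's numbering, 1669 were also missing from the file, where 151 would be shared by chance. The table holds no HY5 symbol. Mp1g16800, listed as MpBZIP1, was taken as MpHY5 from published nomenclature, and this identity was not tested here.

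The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1) with 4 group means over all 12 libraries, 8 residual degrees of freedom, and the trend and robust options of its empirical Bayes step. Genes with a value of at least 1 in at least 3 libraries entered, which left 15999 genes. The 5 contrasts were the UV-B response of each line, the difference of these responses, and Mphy5 against wild type without and with UV-B. Genes past a Benjamini-Hochberg adjusted p of 0.05 are said to be called, and fold changes are on the log2(value + 1) scale. For low genes the pseudocount pulls a fold towards 0, and averaging logs of variable values can move it away from the ratio of the means in either direction, so such folds are approximate. Fold changes of genes at 0 in a whole group are given as lower bounds against the floor of 3 reads per library.

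Before the data were examined, 24 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists had been defined by descriptions, and because the name table gives only symbols, their members were taken by symbol before any fold change was computed. Light-harvesting proteins, early light-induced proteins and cytosolic ribosomal proteins had no symbols and were not tested. The photolyase and repair list was reduced to MpRAD5, MpRAD54 and MpDDB1, and the reference genes to MpACTIN7, MpEF1 and MpAPT. Lists were tested with camera from limma with its preset correlation of 0.01 and with an estimated correlation, and p-values were adjusted over the 120 tests of 24 lists in 5 comparisons.

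By the naming rule, each comparison names up to 10 rises and 10 falls with symbols and up to 2 of each without symbols, by size of change. These had to be called, with a mean of at least 51.63 normalized reads (the 25th percentile of tested genes) in the higher group and no overlap between the replicates of the groups compared. For the difference of responses, the sign had instead to be kept without each library in turn. MpBZIP1 and up to 4 members of each list with the smallest adjusted p were also named. Genes chosen after their values were seen are said to be so.

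The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5, TMM and median-ratio rescaling, a fit of only the groups compared, the replicate number as a block, each library left out in turn, a 2-fold minimum, and limma without trend and robust options. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. The limma, edgeR and DESeq2 fits and camera were tested on simulated data, the fits with 200 changed genes among 15999. The changed genes were taken only from those with a mean of at least 50, so recovery of lower genes was not tested. At simulated changes of 1.5, 2 and 4 fold, limma recovered 91%, 95.5% and 98.5% in the wild type UV-B contrast and 67.2%, 92.5% and 98.5% in the difference of responses. The false share of calls was 9.5% in the former and 8% in the latter, both above the share that the threshold for calls aims at. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.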

Results

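Transcripts were measured in gemmalings, the young plants that grow from asexual gemmae, of the liverwort Marchantia polymorpha at an age of 7 days. The male wild type Tak-1 and a Mphy5 mutant were each sampled with and without 3 h of UV-B at 1.5 µmol per square metre per second, added to white light of 50 µmol. The sample titles give the hours of UV-B but no hour of harvest. If the samples without UV-B were taken 3 h earlier, each UV-B contrast would also hold effects of elapsed time, which was not tested. HY5 is a bZIP transcription factor that acts in flowering plants downstream of the UV-B photoreceptor UVR8. Each of the 4 groups had 3 libraries. Recovered reads per library numbered 53402411 to 59014654 in wild type without UV-B, 48069880 to 53240381 in wild type with UV-B, 49805116 to 66735107 in Mphy5 without UV-B and 44787979 to 67532310 in Mphy5 with UV-B. Between 2682 and 3052 of the 18255 genes were at 0 in a library, and the 10 most abundant genes took 6.23% to 6.91% of the values. Transcripts of the 92 genes of the male V chromosome summed to group means of 143900 to 161709 normalized reads, and those of the 63 genes of the female U chromosome to 79 to 171 recovered reads per library, as for male plants in both lines.

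The targeted gene was examined first. MpBZIP1 (Mp1g16800), taken here as MpHY5, stood at 1418, 1319 and 1281 normalized reads in wild type without UV-B and at 5999, 6354 and 5745 with UV-B. In Mphy5 it stood at 1592, 1522 and 1521 without UV-B and at 16018, 16815 and 15534 with UV-B. Its transcript was thus present in every library of the mutant. The kind of mutation is not given in the sources used here, and a small lesion can leave a transcript in place, so this level does not check the mutant's label. In limma, MpBZIP1 rose 4.5-fold with UV-B in wild type (log2 fold change 2.17, SE 0.05, adjusted p = 2.4e-17) and 10.4-fold in Mphy5 (3.38, SE 0.05, adjusted p = 1.7e-20). The mutant's level was 1.15-fold that of wild type without UV-B (adjusted p = 0.0056) and 2.67-fold with UV-B (adjusted p = 5.9e-14).

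**Figure D1:**
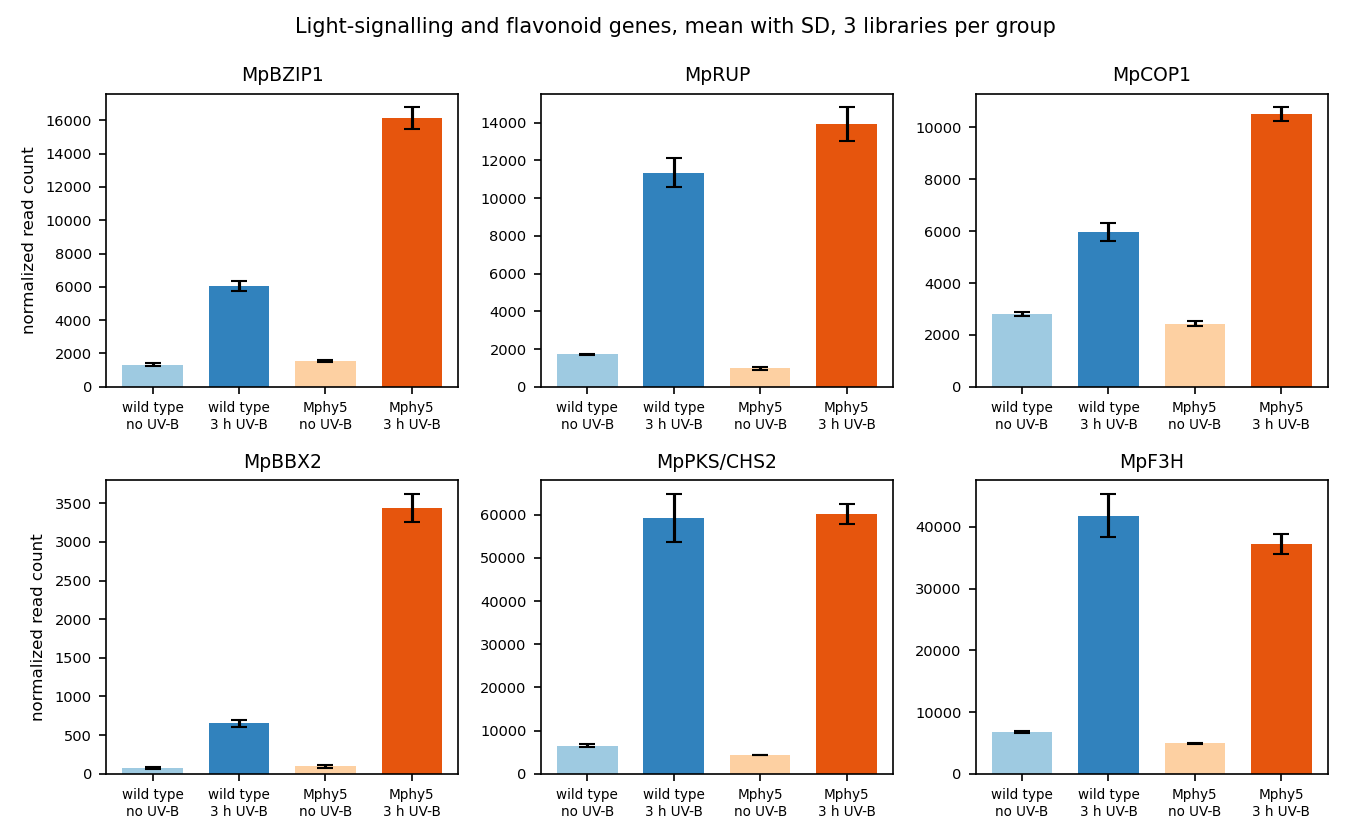
Bars give the mean normalized read count of 6 genes in wild type without and with UV-B (light and dark blue) and in Mphy5 without and with UV-B (light and dark orange), and error bars give the SD of 3 libraries. MpBZIP1 reached 6033 in wild type and 16120 in Mphy5 with UV-B, whereas MpPKS/CHS2 reached 59160 and 60080.

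The first question was which genes respond to 3 h of UV-B in wild type gemmalings. Genes of the flavonoid pathway and of the UV-B signalling module were among the largest rises with symbols, beside a dehydrin, an expansin and a zinc finger gene. Among the falls were lipoxygenases, peroxidases and a second group of chalcone synthase and phenylalanine ammonia-lyase genes. limma called 4674 of 15999 genes (29.2%), 2331 up and 2343 down, and of these 480 rose and 176 fell at least 2-fold.

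The pigment branch gave several of the largest rises in wild type. MpPKS/CHS2 (Mp2g07060), of the chalcone synthase family that opens flavonoid synthesis, rose from 6499 ± 305 to 59160 ± 5530 normalized reads (SD, n = 3; log2 fold change 3.18, limma adjusted p = 3.4e-19). MpAUS (Mp2g05850), an aurone synthase of red pigment formation, rose from 21.9 ± 10.2 to 432.5 ± 77.5 (4.35, adjusted p = 1.2e-09). MpDFR-like19 (Mp8g08710), related to dihydroflavonol reductases, rose by 2.69 on the log2 scale (adjusted p = 5e-10). MpF3H (Mp1g26540), a flavanone hydroxylase, rose from 6848 ± 168 to 41800 ± 3460 and MpCHIL2, a chalcone isomerase-like protein, by 2.36 (adjusted p = 1.4e-18). MpPAL1, an entry enzyme of the phenylpropanoid pathway, rose by 1.81 (adjusted p = 3.4e-09) and MpC4H1 by 0.60.

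Several genes of the UV-B signalling module rose as well. MpRUP (Mp2g18040), whose relatives in flowering plants switch off UVR8, rose 6.58-fold from 1722 ± 31.2 to 11350 ± 783 (adjusted p = 9.9e-18). MpCOP1 (Mp5g12010), a ubiquitin ligase of light signalling, rose from 2803 ± 71.4 to 5969 ± 346 (log2 fold change 1.09, adjusted p = 3.9e-13), and MpCRY-DASH, of the cryptochrome and photolyase family, by 2.23 (adjusted p = 4.2e-15). The B-box gene MpBBX2 (Mp3g20050) rose from 73.8 ± 17 to 653.9 ± 46.9 (3.16, adjusted p = 1.4e-12). MpUVR8 itself, chosen after its values were seen, had a log2 fold change of -0.04 and was not called. Other large rises were those of the zinc finger gene MpC2H2-21 (3.66), the dehydrin MpDHN1 (2.89), MpExpansin20 (2.76), the pentatricopeptide repeat gene MpPPR_16 (2.74, adjusted p = 1.1e-14) and MpEXL9 (2.66). Mp4g18580, which has no symbol, was at 0 without UV-B and at a mean of 59.8 with it, at least 20.3-fold higher. Its neighbour Mp4g18590 went from 0.343 to 76.8 normalized reads.

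A different set of metabolic genes fell in wild type. MpPKS/CHS14 (Mp4g14190) fell from 2934 ± 204 to 1073 ± 40.6 (log2 fold change -1.45, limma adjusted p = 1.8e-13) and MpPKS/CHS15 (Mp4g14200) from 2627 ± 180 to 891.2 ± 60.2 (-1.56, adjusted p = 1.7e-07). MpPAL4 (-1.59) and MpPAL-like2 (-1.45) also fell, so that 1 part of the phenylpropanoid and chalcone synthase families rose while another part fell. The lipoxygenase MpLOX16 fell from 84.8 to 24.4 (adjusted p = 0.00042), the peroxidases MpPOD26 and MpPOD68 had log2 fold changes of -1.60 and -1.53, and MpPTB3 and Mp4g01460 of -1.87 and -2.84. MpCYP704-like11 (-1.65, adjusted p = 0.014) lost its call without wild type replicate 2 without UV-B (0.0778) and without wild type replicate 3 with UV-B (0.0786). Members of these families can share reads with near-identical copies, and the counting of such reads is not given in the sources used here, so values of single PKS/CHS, POD, LEA and histone genes are uncertain.

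As groups in wild type, the light receptors and their factors and the later flavonoid enzymes moved up. Of 10 measured light-signalling genes 7 rose and 1 fell, and 7 and 1 when adjusted over the list alone (camera adjusted p = 7.48e-06; adjusted p = 0.754 with an estimated correlation). Among 28 later flavonoid enzymes 16 rose, 3 fell and 9 were not called, and 16 and 5 did so adjusted over the list alone (camera adjusted p = 0.000324; adjusted p = 0.754 with an estimated correlation). Antioxidant enzymes had 16 rises and 4 falls among 46, and the same numbers adjusted over the list alone (camera adjusted p = 0.0446; adjusted p = 0.835 with an estimated correlation), led by the glutathione peroxidases MpGPX2 (1.04) and MpGPX1 (0.70). Their call was lost without wild type replicate 1 (0.0551) or 3 (0.0504) without UV-B, wild type replicate 1 (0.0542) or 3 (0.0575) with UV-B, Mphy5 replicate 3 without UV-B (0.0502), or Mphy5 replicate 1 (0.0541), 2 (0.0503) or 3 (0.053) with UV-B.

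Lists that moved down in wild type were those of jasmonate synthesis and of dividing cells. None of 20 jasmonate and oxylipin genes rose and 7 fell, and 8 fell adjusted over the list alone (camera adjusted p = 0.00819; adjusted p = 0.835 with an estimated correlation), among them MpLOX2 (-0.79), MpLOX7 (-0.97) and the allene oxide synthase MpCYP74N2 (-0.56). Histones, cyclins and replication genes had 3 rises and 21 falls among 40, and 3 and 25 adjusted over the list alone (camera adjusted p = 0.00305; adjusted p = 0.835 with an estimated correlation), with a median log2 fold change of -0.21. In all, 20 of the 120 list tests passed with the preset correlation and 0 with the estimated one, and 37 and 7 had an unadjusted p under 0.05 in camera. The call of a list therefore rests on the preset correlation throughout, while the counts of single genes do not.

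The other lists were not called in wild type. Rises and falls were 2 and 5 of 16 in phenylpropanoid entry (2 and 6 adjusted over the list alone, camera adjusted p = 0.478) and 4 and 7 of 26 in the chalcone synthase family (4 and 9 adjusted over the list alone, 0.253). They were 8 and 21 of 146 in peroxidases (0.0623), 5 and 14 of 44 in expansins and rhizoid factors (0.0713), 6 and 9 of 35 in auxin genes (0.655), 12 and 21 of 108 in cytochrome P450 genes (0.458), 6 and 9 of 35 in UDP-glycosyltransferases (0.886) and 0 and 3 of 43 in polyphenol oxidases (0.534). MYB factors had 5 rises and 8 falls among 48 (0.99), AP2/ERF and WRKY factors 9 and 10 among 36 (0.615), B-box proteins 2 and 2 among 6 (0.942) and clock genes 3 and 1 among 8 (0.251). Heat shock proteins had 2 and 1 of 6 (0.882), terpene synthases 1 and 4 of 24 (0.251), photosystem and chlorophyll genes 1 and 0 of 5 (0.501), and carotenoid genes 1 and 0 of 5 (0.882). Among repair genes 0 of 3 were called (0.996), among sexual organ genes 1 of 5 fell (0.547) and among reference genes 0 of 3 were called (0.886). Single members of these lists still changed, such as MpUGT9 (2.21), MpCYP94L1 (1.95), MpCYP813-like3 (1.17), the clock gene MpPRR (1.02), the chlorophyll gene MpGUN5 (0.80), the auxin receptor MpTIR1 (-0.54) and the auxin transporter MpPIN1 (-0.40).

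The second question was whether UV-B still acts in the Mphy5 mutant. Most changes called in wild type were called there too, with 76.3% of all rises and 67.5% of all falls in the same direction. limma called 5087 genes (31.8%), 2538 up and 2549 down, and 531 rose and 221 fell at least 2-fold. Flavonoid enzymes and UV-B signalling genes were again among the largest rises with symbols. The largest rise among genes that met the naming rule was that of Mp6g14520, which has no symbol. After TMM rescaling the split was 2728 up and 2329 down.

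MpBBX2 had the largest rise in Mphy5 among genes with a symbol that met the naming rule, from 95.6 ± 15.2 to 3434 ± 179 normalized reads (log2 fold change 5.16, limma adjusted p = 4.5e-16). MpRUP rose 14.2-fold from 980.7 ± 71.1 to 13900 ± 900 (adjusted p = 2e-20), and MpPKS/CHS2 rose from 4309 ± 5.03 to 60080 ± 2310 (13.9-fold, adjusted p = 1.5e-20). MpF3H rose from 4924 ± 133 to 37250 ± 1630 (2.92, adjusted p = 2.3e-19), MpAUS by 3.96, MpDHN1 by 3.86, MpPPR_16 by 3.20 and MpR2R3-MYB14, a MYB factor, by 2.86 (adjusted p = 1.7e-05). MpCOP1 rose by 2.11, MpCRY-DASH by 2.27, MpCHIL2 by 2.29, MpPAL1 by 2.59 and MpPRR by 1.69. Without symbols, Mp6g14520 rose from 600.6 to 22590 and Mp2g25900 by 4.89 on the log2 scale. The transporter gene MpABCG29 (3.57, adjusted p = 0.02) lost its call without Mphy5 replicate 1 with UV-B (0.0622) and with a pseudocount of 0.1 (0.0686).

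The largest falls in Mphy5 with symbols included dioxygenase and lipoxygenase genes. MpDOXC28, an oxoglutarate-dependent dioxygenase, fell from 1039 ± 6.37 to 286.3 ± 65 (log2 fold change -1.88, adjusted p = 1.4e-10) and the lipoxygenase MpLOX14 from 12050 ± 1390 to 4282 ± 355 (-1.49, adjusted p = 8.2e-08). MpLOX16 (-1.66), MpPAL4 (-1.52), MpIDA4 (-1.46), MpPTB8 (-1.43), MpGT37.5 (-1.39), the bHLH gene MpBHLH40 (-1.38) and MpCupin82 (-1.35) followed. Mp5g16240 (-2.25) and Mp8g04250 (-2.20) fell most among genes without symbols that met the naming rule. Auxin genes included MpPIN1 (-1.02), MpAUX1 (-0.71), MpTIR1 (-0.68) and MpSAUR2 (-0.96).

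In Mphy5 the same light and flavonoid lists were called. Light-signalling genes had 7 rises and 1 fall among 10, and as many adjusted over the list alone (camera adjusted p = 7.48e-06; adjusted p = 0.754 with an estimated correlation). Later flavonoid enzymes had 17 rises and 6 falls among 28, and 17 and 7 adjusted over the list alone (camera adjusted p = 0.000893; adjusted p = 0.754 with an estimated correlation). Jasmonate genes had 0 rises and 6 falls among 20, and as many adjusted over the list alone (camera adjusted p = 0.0395; adjusted p = 0.835 with an estimated correlation), a call lost without Mphy5 replicate 1 without UV-B (0.076) or replicate 2 with UV-B (0.0521). Dividing-cell genes had 5 rises and 9 falls among 40 and were not called (0.375). Neither were antioxidant enzymes with 15 and 3 of 46 (0.0623, and 0.0481 after TMM rescaling), the chalcone synthase family with 2 and 8 of 26 (0.296), or auxin genes with 5 and 12 of 35 (0.11). Among reference genes 1 of 3 fell, and 2 adjusted over the list alone, while the list was not called (0.547). The gene that fell was MpACTIN7, a call lost in 3 alternatives.

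The third question was whether the UV-B response differs between the lines. Most of the response did not differ detectably, and a set of signalling genes rose further in the mutant. The difference of responses was called for 714 genes (4.46%), with 308 more positive and 406 more negative in Mphy5, and 32 and 24 of these differed at least 2-fold. The excess of negative differences turned after TMM rescaling (362 more positive and 348 more negative) and without replicate 1 of Mphy5 without UV-B (386 and 343). limma without its trend and robust options called 332.

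Of the 480 genes that rose at least 2-fold in wild type, 386 (80.4%) were also called up in Mphy5, 332 of them at least 2-fold, and 0 were called in the opposite direction. The difference was not called for 397 of them, 57 rose more in Mphy5 and 26 had a smaller or opposite response. Of the 176 genes that fell at least 2-fold in wild type, 74 (42.0%) were also called down in Mphy5, while the difference was called for 12 with a smaller and 1 with a larger fall and not called for 163. Over all 2343 genes called down in wild type, 1582 (67.5%) were also called down in Mphy5, and the balance was the reverse, with 138 larger and 59 smaller or opposite responses in Mphy5. Median log2 fold changes were 1.55 in wild type and 1.45 in Mphy5 for the rises, and -1.40 and -0.70 for the falls of at least 2-fold, but -0.31 and -0.30 over all called falls. Choosing genes on the wild type fold can enlarge the wild type medians. With genes chosen without the wild type libraries that gave the fold, the mean medians of the rises were 1.41 in wild type and 1.45 in Mphy5. Those of the falls of at least 2-fold were -1.05 and -0.66. When genes were chosen by Mphy5 instead, 103 of 531 rises and 112 of 221 falls of at least 2-fold were not called in wild type. The response was larger in Mphy5 for 111 of the 531 and 39 of the 221. Across the 4674 genes called in wild type, the log2 fold changes of the lines had a Pearson correlation of 0.839 and a Spearman correlation of 0.871, and over all tested genes 0.547 and 0.519. These correlations are across genes, which are not independent replicates, and no library entered both responses.

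**Figure D2:**
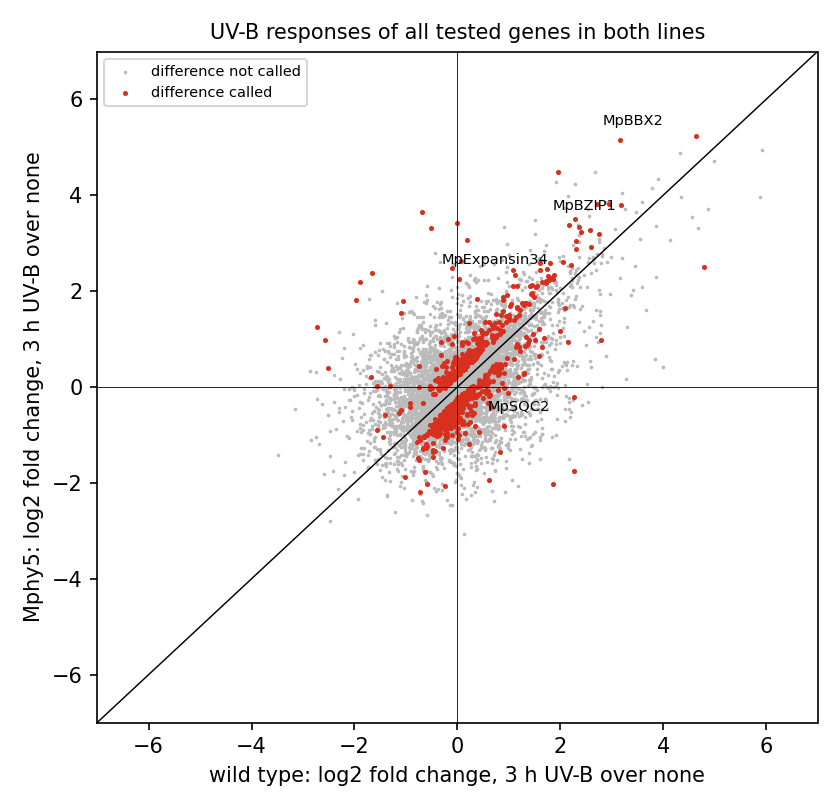
Each point is a tested gene, with its log2 fold change after UV-B in wild type on the horizontal axis and in Mphy5 on the vertical axis, and the line marks equal responses. The 714 genes whose responses differed in limma are red, and MpBBX2 lies above the line with 3.16 in wild type and 5.16 in Mphy5.

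Some components of UV-B and light signalling rose more in the mutant, while others did not differ detectably, such as MpCRY-DASH with a difference of 0.03 (adjusted p = 0.93). MpBBX2 had a difference of 2.01 on the log2 scale (SE 0.22, limma adjusted p = 1e-05), MpBZIP1 of 1.21 (SE 0.07, adjusted p = 1.1e-08), MpRUP of 1.11 (adjusted p = 1.9e-07) and MpCOP1 of 1.02 (adjusted p = 3.5e-08). MpDET1 (Mp8g00970), a repressor of light responses in flowering plants, went from 4908 ± 240 to 9134 ± 623 in wild type and from 4362 ± 132 to 15350 ± 690 in Mphy5 (0.92, adjusted p = 3.4e-07). The clock gene MpPRR (0.67, adjusted p = 1.6e-05), MpBBX3 (0.65) and MpBBX1 (0.29) also rose more. In the pigment pathway, MpPAL1 (0.78, adjusted p = 0.0032) and MpPKS/CHS2 (0.62, adjusted p = 7.3e-05) had larger rises in Mphy5, both from a lower level. With UV-B, MpPKS/CHS2 ended at a level similar to wild type, and MpPAL1 at a log2 ratio of -0.2 to wild type.

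Genes outside light signalling and pigment synthesis differed in their response as well. MpExpansin34 (Mp4g22180) stood at 159.5 ± 39.3 and 161.9 ± 40.6 in wild type and went from 368.9 ± 130 to 1695 ± 146 in Mphy5 (difference 2.23, adjusted p = 0.0055). MpCKX2, a cytokinin oxidase gene, went from 645.1 ± 133 to 605.2 ± 35.4 in wild type and from 135.1 ± 16.8 to 284.3 ± 19.3 in Mphy5 (1.14, adjusted p = 0.0016). MpLEA-like18 (1.35), MpGST30 (0.97) and MpPOD169 (0.94) were also more positive, as were Mp6g01910 (2.59) and Mp4g14850 (2.56). MpSQC2 (Mp8g14150) went from 459.7 ± 89 to 877.2 ± 215 in wild type and from 63.5 ± 12.9 to 36.3 ± 9.89 in Mphy5 (-1.72, adjusted p = 0.0023). MpHCT, a hydroxycinnamoyl transferase gene, went from 14690 ± 919 to 12370 ± 388 in wild type and from 16090 ± 1710 to 7448 ± 848 in Mphy5 (-0.87, adjusted p = 0.00095). The auxin transporter genes MpAUX1 (-0.83, adjusted p = 1.9e-07) and MpPIN1 (-0.62, adjusted p = 4.2e-06), the chitinase-family gene MpGH19.7 (-0.89), the dioxygenases MpDOXC15 (-0.93) and MpDOXC28 (-0.86), the F-box gene MpKFB01_20 (-0.86) and Mp5g20350 (-2.28) were more negative.

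Among the lists, 3 were called in the difference of responses. Light-signalling genes had 3 more positive and 1 more negative among 10, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.000763; adjusted p = 0.835 with an estimated correlation). The targeted gene MpBZIP1 belongs to this list and was among its more positive members, and 6 members were not called. Auxin genes had 0 and 2 among 35, and as many adjusted over the list alone (camera adjusted p = 0.0269; adjusted p = 0.835 with an estimated correlation), a call lost without replicate 1 of wild type without UV-B (0.0777), replicate 2 of wild type with UV-B (0.0524), replicate 1 of Mphy5 without UV-B (0.056) or replicate 3 of Mphy5 with UV-B (0.0806). Dividing-cell genes had 1 and 1 among 40, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.0279; adjusted p = 0.839 with an estimated correlation), such as MpCYCD_1 (0.43) and MpH2B.1 (-0.31). This last call was lost without wild type replicate 1 (0.0884) or 3 (0.0537) without UV-B, wild type replicate 1 (0.0502) or 2 (0.285) with UV-B, Mphy5 replicate 3 without UV-B (0.0659), or Mphy5 replicate 1 (0.0702) or 3 (0.0806) with UV-B. Later flavonoid enzymes had 1 and 1 among 28, with 2 and 1 adjusted over the list alone, and were not called (0.882), so no difference of this branch as a group was detectable.

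The fourth question was how the mutant differs from wild type without UV-B. Many genes differed strongly, and the largest differences with symbols included peroxidase, pathogenesis-related and terpene synthase genes. limma called 3986 genes (24.9%), 1764 higher and 2222 lower in Mphy5, and 453 and 376 of these at least 2-fold. Because a single mutant line was sampled, these differences belong to that line and not necessarily to the loss of MpHY5.

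Several genes were present in 1 line and nearly absent from the other. MpASLBD1, of the LOB-domain transcription factors, was at 0 in wild type and at 207.6 ± 37.9 normalized reads in Mphy5, at least 70.5-fold higher. The terpene synthase MpTPS6 (Mp3g13150) was at 248.6 ± 48.7 in wild type and at 0 in Mphy5, at least 92.8-fold lower. Without symbols, Mp6g10280 was at least 387-fold higher, Mp8g04945 at least 522-fold lower and Mp3g07970 at least 350-fold lower, and Mp7g06490 stood at 0.343 in wild type and 1872 in Mphy5. MpCYP704-like8 was among the largest differences, at 31.3 ± 10.3 against 1731 ± 79.1 (log2 fold change 5.79, limma adjusted p = 4.7e-15), as were the pathogenesis-related genes MpPR6c (6.24, adjusted p = 0.0011) and MpPR6b (3.14). MpPOD49, a peroxidase gene, was 32.1-fold higher, and the peroxidases MpPOD73 (4.07), MpPOD76 (3.91) and MpPOD4 (3.41), MpFBW3 (3.40) and the chitinase-family gene MpGH19.3 (3.30) were higher too. Lower in Mphy5 were the wall-associated kinase gene MpRLK-Pelle_WAK1 (-7.27), the terpene synthase-like MpMTPSL22 (-6.34), MpPOD13 (-4.69), MpCupin85 (-4.59), MpPR1 (-2.94), MpSQC2 (-2.84, adjusted p = 1e-08), the polyphenol oxidase MpPPO10 (-2.44), MpOMT4 (-2.39) and MpCIS6 (-2.37).

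Several genes of the UV-B response differed between the lines without UV-B, although the light-signalling list, with 1 higher and 3 lower among 10, was not called (camera adjusted p = 0.299). MpRUP (-0.81, adjusted p = 3.9e-09), MpCRY-DASH (-0.87, adjusted p = 3.2e-08), MpPAL1 (-0.97, adjusted p = 4.5e-06), MpPKS/CHS2 (-0.59, adjusted p = 1.3e-07), MpF3H (-0.48) and MpCOP1 (-0.20, adjusted p = 0.0039) were lower in Mphy5. MpPKS/CHS14 (0.67, adjusted p = 7.8e-08) and MpPKS/CHS17 (1.53) were higher.

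Called lists without UV-B pointed mostly up in Mphy5. The chalcone synthase family had 13 higher and 1 lower among 26, and as many adjusted over the list alone (camera adjusted p = 0.000324; adjusted p = 0.754 with an estimated correlation). AP2/ERF and WRKY factors had 12 and 2 among 36, and 13 and 2 adjusted over the list alone (camera adjusted p = 0.00388; adjusted p = 0.754 with an estimated correlation), such as MpERF17 (1.87, adjusted p = 4.1e-08), MpWRKY14 (1.72) and MpERF14 (1.20). Dividing-cell genes had 13 and 2 among 40, and as many adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.835 with an estimated correlation), led by the cyclin MpCYCD_2 (1.18, adjusted p = 1.3e-09). Expansins and rhizoid factors had 5 higher and 20 lower among 44, and 6 and 20 adjusted over the list alone (camera adjusted p = 0.0244; adjusted p = 0.835 with an estimated correlation), such as MpCSLD5 (-0.88) and MpExpansin16 (-0.51). Jasmonate genes had 8 higher and 1 lower among 20, and as many adjusted over the list alone (camera adjusted p = 0.0395; adjusted p = 0.835 with an estimated correlation), including MpLOX7 (0.78) and the repressor MpJAZ (0.32). That call was lost without wild type replicate 1 (0.078) or Mphy5 replicate 1 (0.116) without UV-B, or Mphy5 replicate 1 (0.0541), 2 (0.0521) or 3 (0.053) with UV-B. Peroxidases had 39 higher and 19 lower among 146, and 42 and 21 adjusted over the list alone, but were not called as a list (0.0629), and later flavonoid enzymes had 4 and 8 among 28 (0.431).

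**Figure D3:**
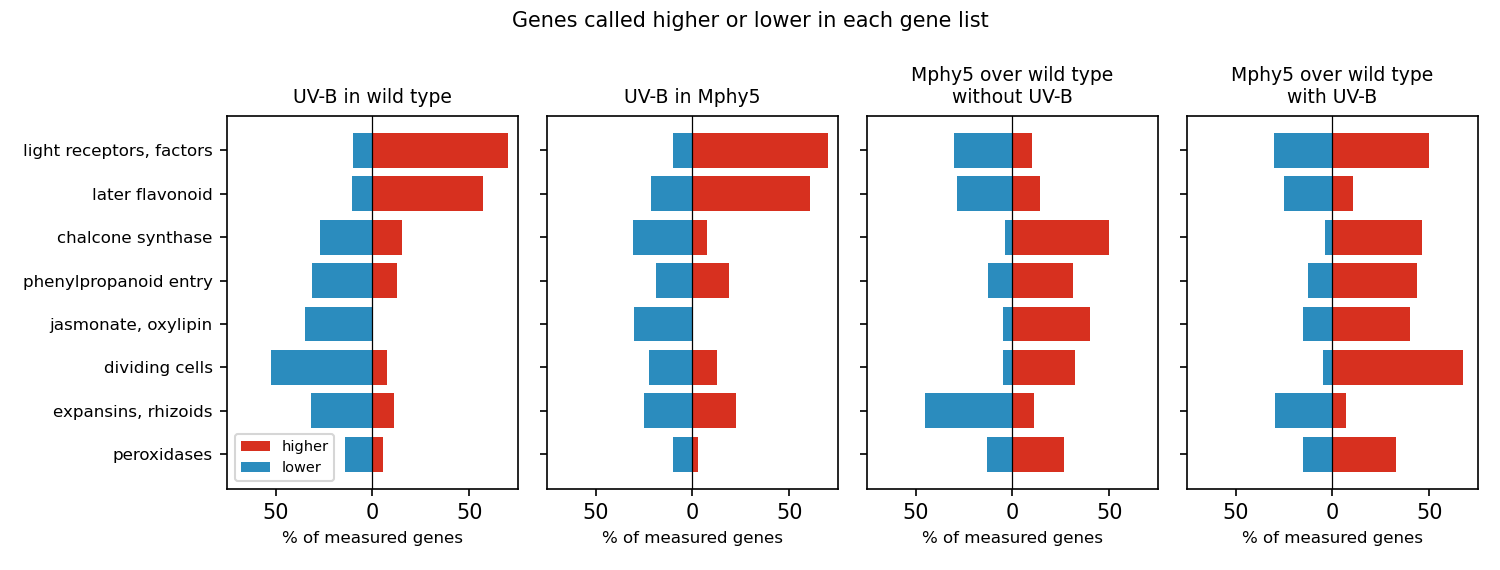
Each panel is a comparison and each bar gives the percent of a list's measured genes called higher (red, to the right) or lower (blue, to the left) in limma, for 8 gene lists. In the panels of Mphy5 against wild type, 13 of 40 dividing-cell genes were higher without UV-B and 27 with UV-B.

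The last comparison set Mphy5 against wild type after UV-B. The line differences seen without UV-B mostly returned, with 254 of 395 genes at least 4-fold apart again so. limma called 4766 genes (29.8%), 2209 higher and 2557 lower in Mphy5, and 511 and 446 of these at least 2-fold. TMM rescaling turned the excess, with 2437 higher and 2357 lower.

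After UV-B, MpASLBD1 was at least 55.4-fold higher in Mphy5, and MpPR6c (log2 fold change 6.67), MpCYP704-like8 (5.50, limma adjusted p = 7e-15), MpPOD49 (4.53), the resistance-type gene MpNBS-LRR11 (4.46), MpPOD73 (4.20), MpPOD76 (3.70), MpPOD126 (3.60) and MpPOD114 (3.26) were higher. MpExpansin34 was at 161.9 ± 40.6 in wild type and 1695 ± 146 in Mphy5 (3.41, adjusted p = 1.8e-06), and MpBBX2 was higher by 2.39 (adjusted p = 3.1e-10). MpCOP1 was higher by 0.82 (adjusted p = 9.8e-11) and MpRUP by 0.29 (adjusted p = 0.00091), while MpCRY-DASH (-0.83) and MpAUX1 (-0.89, adjusted p = 9.9e-12) were lower. MpTPS6 stood at 638.5 ± 159 in wild type and 0.667 ± 0.608 in Mphy5. MpSQC2 was 23.6-fold lower (adjusted p = 7.5e-12), and MpRLK-Pelle_WAK1 (-5.25), MpMTPSL22 (-5.16), MpPOD13 (-4.29), MpOMT4 (-4.18), MpPPO10 (-2.64), the glycosyltransferase-family gene MpGT37.3 (-2.62), MpGH19.7 (-2.54) and MpCupin85 (-2.51) were lower. Without symbols, Mp4g19930 stood at 3.72 in wild type and 5158 in Mphy5, Mp3g07970 was at least 302-fold lower and Mp4g20540 at least 259-fold lower.

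Of the lists after UV-B, dividing-cell genes had 27 higher and 2 lower among 40, and 30 and 3 adjusted over the list alone (camera adjusted p = 1.63e-06; adjusted p = 0.835 with an estimated correlation), including MpCYCD_2 (0.82), MpCYCD_1 (0.70) and MpCYCA (0.56), with MpH2B.1 (-0.62) lower. The chalcone synthase family had 12 and 1 among 26, and 13 and 2 adjusted over the list alone (camera adjusted p = 0.000471; adjusted p = 0.754 with an estimated correlation), such as MpPKS/CHS17 (2.48), MpPKS/CHS15 (1.44) and MpPKS/CHS14 (1.08). Peroxidases had 48 and 22 among 146, and 53 and 23 adjusted over the list alone (camera adjusted p = 0.0244; adjusted p = 0.835 with an estimated correlation), a call lost without wild type replicate 3 with UV-B (0.129) or Mphy5 replicate 2 with UV-B (0.0723). Phenylpropanoid entry genes had 7 and 2 among 16, and 8 and 2 adjusted over the list alone (camera adjusted p = 0.0446; adjusted p = 0.835 with an estimated correlation), among them MpPAL-like2 (1.42) and MpPAL8 (0.59). Their call was lost without wild type replicate 2 (0.0674) or 3 (0.0752) with UV-B or Mphy5 replicate 2 with UV-B (0.116). Jasmonate genes, with 8 and 3 among 20 (0.0623), light-signalling genes, with 5 and 3 among 10 (0.241), and later flavonoid enzymes, with 3 and 7 among 28 (0.39), were not called.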

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

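The plain splits and relabellings of the samples and the search for a mislabelled library were set before the result was seen, and every other test in this part, the relabelling with additive effects removed among them, was chosen afterwards. The results given here are those in which limma's test of the difference between the UV-B responses of the lines was past the threshold. It called 714 genes. The log2 difference, Mphy5 minus wild type, was 2.23 for MpExpansin34, 2.01 for MpBBX2, 1.35 for MpLEA-like18, 1.21 for MpBZIP1, 1.14 for MpCKX2, 1.11 for MpRUP, 1.02 for MpCOP1, 0.97 for MpGST30, 0.94 for MpPOD169 and 0.92 for MpDET1. It was -1.72 for MpSQC2, -1.12 for MpGH19.9, -1.08 for MpCYP829-like14, -1.01 for MpNPF9, -0.96 for MpLEA-like33, -0.93 for MpDOXC15, -0.89 for MpGH19.7, -0.87 for MpHCT, -0.86 for MpKFB01_20 and -0.86 for MpDOXC28. Without symbols it was 2.59 for Mp6g01910, 2.56 for Mp4g14850, -2.47 for Mp4g19400 and -2.28 for Mp5g20350. The list medians were 0.099 for light-signalling genes, -0.06 for auxin genes and 0.148 for dividing-cell genes. With an estimated correlation these lists were not called (camera adjusted p = 0.835, 0.835 and 0.839). Their calls with the preset correlation were kept in 12, 8 and 5 of 12 fits with 1 library left out.

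Several of the gene calls were lost when single libraries were left out. MpGH19.9 lost its call without wild type replicate 3 without UV-B (adjusted p = 0.0536) or Mphy5 replicate 2 without UV-B (0.0675), and MpLEA-like33 without wild type replicate 1 without UV-B (0.05). MpCYP829-like14 lost it without wild type replicate 3 without UV-B (0.0696), wild type replicate 1 with UV-B (0.0718), Mphy5 replicate 2 without UV-B (0.0611) or Mphy5 replicate 2 with UV-B (0.0607). Mp4g19400 lost it without Mphy5 replicate 2 without UV-B (0.0604) or Mphy5 replicate 1 with UV-B (0.0517), and with a pseudocount of 0.1 (0.15). MpNPF9 kept its call only without wild type replicate 2 without UV-B, wild type replicate 3 with UV-B or Mphy5 replicate 3 with UV-B. Without each of the other libraries its adjusted p lay between 0.0555 and 0.114, and with the replicate number as a block it was 0.0559.

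For the comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real split called 4674 genes in wild type with UV-B against without, where the highest other split called 0. The values were 5087 and 1 for Mphy5 with against without UV-B, 3986 and 0 for the lines without UV-B, and 4766 and 0 for the lines with UV-B. For the difference of responses, 7 of 100 relabellings gave at least 714 genes and the highest other gave 6106. Relabellings of that kind put the lines in unequal numbers into the contrast, so they read the large differences between lines, a structure of the samples. With the additive effects of line and UV-B removed, only the real labelling, 1 of 100, reached 714 and the highest other gave 3. This test was chosen after the plain relabelling had not argued against chance. The effects were removed by the real labels, which leaves the real contrast untouched but takes line differences out of unequal relabellings. The relabelling with 6106 had to fall to 0, so the test cannot decide whether the 714 arose by chance.

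The first pattern is the set of genes at least 4-fold apart between the lines without UV-B, 395 in all, of which 254 were as far apart in the same direction with UV-B and 2 were called in the opposite direction. Of the 254, 13 were at 0 in every wild type library and 17 in every Mphy5 library. A swap of the line label among the UV-B libraries is argued against by 0 of 6 lying nearer to the other line. The line labels of the libraries without UV-B, which set the genes and the means, and the treatment labels were not tested. Mutant reads that failed to align cannot explain the 142 genes higher in Mphy5. Blocks of the genome from another parent cannot be told apart from local clusters of related genes, since 119 of 249 genes lay within 5 genes of another (at most 57 with permuted positions), while loci merged over that distance had a variance over mean of 1.17 per bin of 100 genes (0.82 to 1.24 with permuted positions). For the 112 genes lower in Mphy5, lost alignments and real loss of transcript cannot be told apart because no reads were used here, and loss of MpHY5 is a candidate explanation that 1 mutant line does not separate from other differences between the lines.

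The second pattern is the 57 induced genes, MpBZIP1, MpRUP, MpCOP1 and MpBBX2 among them, that rose more in Mphy5, with a median log2 difference of 0.55. TMM rescaling left all 57 called with a median difference of 0.57 and changed the calls of 112 other genes. It raised the difference of each of the 57 by only 0.019 to 0.02. A shift this small and upward could hardly remove these calls, so TMM rescaling cannot decide whether scaling of the libraries is the cause. A scaling factor per library, however, moves the difference of every gene by about the same amount. The differences of the 57 ran from 0.29 to 2.53, and the median of all other tested genes was 0. These values argue against scaling as the whole cause of the 57 larger rises. A shift of all transcripts together would be removed by either scaling and was not measured. In these libraries, 42 of the 57 genes were lower in Mphy5 without UV-B, and the median log2 ratio of the lines was -0.39 without and 0.19 with UV-B. Choosing genes by a positive difference moves the first value down and the second up, and no choice from other libraries was made. A lower start in the mutant with an equal level after UV-B is argued against as the whole cause for the 28 genes that stood higher in Mphy5 with UV-B (13 of them also started lower), and for the other 29 it cannot be told apart from a stronger induction, because a larger rise that does not end higher must start lower. A hypothesis that rests on 1 mutant line and on Mp1g16800 being MpHY5 is that MpHY5 may restrain its own transcript after UV-B, which another allele or a complemented line would test and these data do not.

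The third pattern is the weaker fall in Mphy5 of the 176 genes that fell at least 2-fold in wild type, with medians of -1.40 and -0.70; it is limited to these genes, of which 97 reached the 25th percentile of expression, since over all 2343 called falls the medians were -0.31 and -0.30 and more responses were larger in Mphy5 (138) than smaller or opposite (59). Selection of genes on noise of the wild type libraries is argued against as the whole cause. Choosing genes without the wild type libraries that gave the fold left a mean gap of 0.39, from 0.35 to 0.45 over the replicates left out. That choice still took genes by a large fall in wild type alone, so it cannot decide whether falls are weaker in Mphy5 in general. Over the 176 genes the median log2 ratio of the lines was -0.18 (SE 0.07 from a bootstrap over genes) without UV-B and 0.65 with it, where 77 genes stood higher and 24 lower in Mphy5, but the choice of genes moves both values. That SE treats genes as independent and holds no spread between libraries. With genes chosen without the wild type libraries compared, the mean of the medians was 0.14 without UV-B (-0.02 to 0.28) and 0.5 with it (0.29 to 0.67, SD 0.19), which leans against a lower start in the mutant with an equal level after UV-B, though 3 values this far apart leave it open. The difference of responses was called for only 13 of the 176 genes, and a role of MpHY5 was not tested. Genes chosen by Mphy5 went the other way. Of 221 genes that fell at least 2-fold in Mphy5, 112 were not called in wild type and 39 had a larger fall in Mphy5. The pattern thus belongs to the choice by wild type and is no general weakening of falls in the mutant.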

How the results depend on the processing

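All alternatives given here were listed beforehand, those with edgeR and DESeq2 on the condition that whole reads could be recovered, which the values then showed. Counts of called genes stayed within 1.5 times the main count under each pseudocount, filter, rescaling, block and left-out library and in edgeR and DESeq2, with the exceptions that follow. Which direction had more called genes was not stable in the UV-B responses, with 2331 up and 2343 down in wild type against 2361 and 2351 with a pseudocount of 5, nor under TMM rescaling in Mphy5, in the difference of responses and between the lines with UV-B; the cause was not tested. Requiring a 2-fold change left 656 genes in the UV-B response of wild type, 752 in that of Mphy5, 56 in the difference of responses, 829 between the lines without UV-B and 957 with UV-B, as a stricter criterion must. limma without trend and robust options called 332 genes in the difference of responses, and the cause was not tested. The correlation of the responses across genes was 0.745 with a pseudocount of 0.1, 0.874 with a pseudocount of 5, 0.547 over all tested genes and 0.763 over genes called in either line. Taking in genes without a clear response in any line lowers the value over all tested genes by construction. The genes added by a call in either line were called in Mphy5 but not in wild type. Choosing genes by wild type alone thus gave a higher correlation than choosing by either line. With an estimated correlation 0 of the 120 list tests passed. For the lists with a call, the estimates lay above the preset value, from 0.0332 (AP2/ERF and WRKY factors) to 0.411 (light-signalling genes). The p-values with the preset value therefore assume less correlation than was estimated in these lists. Whether this alone accounts for the lost calls was not tested. Leaving out 1 library at a time gave 3932 (without replicate 2 of wild type without UV-B) to 4788 genes for wild type, 4400 (without Mphy5 replicate 2 without UV-B) to 5233 for Mphy5, and 482 (without the same library) to 729 for the difference. It gave 3041 (again without that library) to 4233 for the lines without UV-B, 3774 (without wild type replicate 1 with UV-B) to 4901 for the lines with UV-B, a correlation of 0.821 to 0.850, and 15 to 25 called lists. MpBZIP1 in wild type stayed between 2.13 and 2.21. Of the 20 list calls 13 were kept without each library in turn and 7 were lost without at least 1, with 0 changes of direction. TMM rescaling gave 21 called lists, and no called list changed direction under it. Median-ratio rescaling moved libraries by at most 1e-04 on the log2 scale, since the values were already scaled that way. It was therefore no separate check of any result. Samples with the same replicate number deviated together at most slightly, with correlations from -0.017 to 0.054 over 18 pairs. All pairs that involved wild type without UV-B were positive, from 0.008 to 0.054, so a small shared effect of the replicate number is not excluded. With the replicate number as a block, 4781, 5146, 779, 4108 and 4835 genes were called in the 5 comparisons, 23 lists passed, the correlation was 0.836 and MpBZIP1 in wild type stood at 2.17. Under the block single calls were lost for MpPKS/CHS13 in wild type (adjusted p = 0.0552), MpPKS/CHS16 in Mphy5 (0.0618), and MpNPF9 (0.0559), MpPKS/CHS15 (0.0915) and MpERF19 (0.0606) in the difference of responses. It added list calls for peroxidases in the wild type response (0.0441) and for photosystem and chlorophyll genes (0.0445) and carotenoid genes (0.0441) between the lines without UV-B. On recovered reads, edgeR called 4748, 5171, 790, 4084 and 4762 genes in the 5 comparisons, sharing 4570, 5000, 701, 3820 and 4593 with limma. DESeq2 called 4866, 5245, 1005, 4220 and 4897, sharing 4607, 5015, 699, 3918 and 4663. Of 8005 values of single named genes under the alternatives, 7780 kept their direction and side of the threshold, 225 lost the call, and 0 reversed. All these pairs were called in the main fit, so a gained call was not possible. Those lost belonged to 46 of 445 pairs of gene and comparison, most often MpERF19 (14 alternatives) and MpUGT9 (11) in the difference of responses. MpPKS/CHS13 in wild type and MpPKS/CHS16 in Mphy5, both among the largest falls, lost their calls in 9 and 8 alternatives and are therefore not described further. Depth limits statements on genes near the floor of 2.34 to 3.58 normalized reads.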

Other observations

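The tests in this part were chosen after the data were seen. Families of genes with a shared symbol were counted among genes called with at least a 2-fold change (of any size for the difference of responses), with one-sided Fisher's exact tests against all tested genes with a symbol. The 118 families gave 1180 tests, of which 12 passed Benjamini-Hochberg adjustment. Without UV-B, 28 of 146 peroxidase (POD) genes were higher in Mphy5 where 6.52 were expected (adjusted p = 5.4e-09), 13 of 32 pathogenesis-related (PR) genes where 1.43 were expected (7.6e-08) and 9 of 48 dirigent (DIR) genes where 2.14 were expected (0.025). The peroxidase list fixed beforehand was not called there (camera adjusted p = 0.0629, and 0.839 with an estimated correlation), and 7 of its genes were at least 2-fold lower. With UV-B, 32 POD genes were higher (8.3 expected, 5.4e-09), 15 PR genes (1.82 expected, 1e-08) and 9 of 25 PKS/CHS genes (1.42 expected, 0.0011). UV-B raised 10 of 56 late embryogenesis abundant (LEA) genes in Mphy5 (2.16 expected, 0.0076) and lowered 4 of 16 LOX genes (0.23 expected, 0.0097) and 4 of 25 PKS/CHS genes (0.36 expected, 0.037) there, and 10 POD genes in wild type (2.4 expected, 0.013). The chalcone synthase list was not called in that response of Mphy5 (camera adjusted p = 0.296), nor the peroxidase list in that of wild type (0.0623). In the difference of responses, 3 of 6 BBX genes were more positive in Mphy5 (0.17 expected, 0.037) and 7 of 41 BHLH genes more negative (1.27 expected, 0.025). The B-box list fixed beforehand was not called in that comparison (camera adjusted p = 0.159; adjusted p = 0.835 with an estimated correlation), and MpBBX5 was more negative by a log2 difference of -0.24 (adjusted p = 0.016), a call lost without wild type replicate 1 without UV-B (0.0507). Genes of a family are not independent, and reads shared between copies would make these p-values too small.

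Genes at least 4-fold apart between the lines in both treatments lay close together. Of 249 such genes on numbered chromosomes, 119 had another within 5 genes, where permuted positions gave a median of 35 and at most 57. For genes changed at least 4-fold by UV-B in wild type the same count was 38 of 189, with a permuted median of 20 and at most 39.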
